A study of Mus musculus with 48 samples.

How the data were processed

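RNA from the whole small intestine of 48 male C57BL/6N mice was hybridised to Agilent mouse gene expression arrays with 2 colours, 1 array per RNA sample and 8 arrays for each of 6 diets. Per the labels, Cy5 marked the RNA of a single sample and Cy3 marked a common reference, an equimolar pool of 47 of the 48 samples, on every array. A ratio of Cy5 over Cy3 is therefore the level of a transcript in that sample relative to the pool, in the same orientation throughout. Per the labels' protocols, total RNA was isolated with Trizol and 200 ng was copied, amplified and labelled. The arrays lay on 6 slides of 8, and every slide held arrays of all 6 diets.

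Per the file headers and the submitters' processing notes, the authors read the scanned images with Agilent Feature Extraction 10.7.3.1. The deposited intensity columns hold the median pixel brightness of each spot and of its local background in each channel, with no normalization. The deposited log10 ratio of Cy5 over Cy3 was, per the file headers, computed by that program after its own background subtraction and dye normalization. The authors also deposited a value table of 50626 features on a log2 scale. Each of its 48 columns had a median of 6.641 and followed the log2 Cy5 median signal of its array with a median r of 0.997 over the 50626 features, against 0.965 for Cy3. It therefore runs in the direction of the Cy5 signal, while its centring and scaling are not given in the sources used here. All 48 columns were matched to a sample through the labels, and 0 columns were left unmatched.

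The starting point was the median signal and median local background of both channels. The choices described here were fixed before the data were examined, unless stated otherwise, and had named mean signals. The files hold median signals, so these were used instead. Background was corrected with normexp at an offset of 50 in limma 3.58.1 under R 4.3.3, and each array was normalized by loess, with control spots at weight 0. The result is a log2 ratio per spot. The 3671 control spots were then left out, as were spots that Feature Extraction marked as outliers in either channel, between 0.322 and 1.01% of an array. Saturated spots were kept. Spots of one probe were averaged, which gave 55681 probes from 59305 spots. A probe was kept when it was well above background in Cy5 on at least 8 arrays, and 31272 probes were. A gene was represented by its kept probe of highest mean intensity. The 5370 genes with more than 1 kept probe were compared across probes, and disagreements are given beside the gene. Files were read with data.table (version 1.17.8), and figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.

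Probes carry accessions and not gene symbols. Of 27752 probes with a RefSeq transcript accession, 27220 matched a symbol in a RefSeq gene table of assembly GRCm38.p6. The submitters' processing notes name build mm9, so positions from that table were not used, and no genome of build mm9 was used here. The 23604 genes and features tested comprise 14832 with a symbol and 8772 known by an accession, a probe name or a position. Members of the Cyp4a, Acot, Defa, Reg3, Mcpt, trypsin, elastase and immunoglobulin families are near copies of one another and their probes may cross-hybridise, so a value for one member is uncertain as to which copy it measures. The same may hold within the Cyp2b, Cyp2c, Cyp3a and Gstm families, which were not named in advance. Cyp2c65 and Cyp2c66, for example, had mean log2 ratios of -0.82 and -0.84 in cHF and of 0.31 and 0.29 in Krill-H.

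A linear model with 1 mean per diet was fitted to all 48 arrays with lmFit and eBayes in limma, so that all comparisons share one estimate of spread. Values of p were adjusted with the Benjamini-Hochberg method over all genes within each of 10 comparisons, at a threshold of 0.05. The labels describe the samples as individual mice. Values of p measure the spread between animals as labelled, and the number of arrays limits the precision of every value.

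In advance, 53 gene lists were written down from general knowledge, 29 of pathways and 24 of cell types or neighbouring tissues. Each was tested with camera in limma at the preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, and adjusted over the 53 lists. Counts within a list are given over all genes and adjusted over the list alone. The preset correlation called too many lists on simulated data, as described next. A list is therefore said to be higher or lower as a group only with the adjusted p at an estimated correlation.

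The calculations were tested on simulated data made by permuting the residuals of the real arrays over 23604 genes, in 10 simulations per comparison with 200 genes changed. At a log2 change of 0.5, between 49.6% (Cal-L vs cHF-F) and 56.3% (Krill-H vs cHF) of the changed genes were found. At 1 the share lay between 92.2% (Cal-L vs cHF-F) and 95.8% (cHF-F vs cHF), and at 2 between 99.5% (Cal-L vs cHF-F) and 100% (Krill-L vs cHF and Krill-L vs cHF-F). The median share of false calls per simulation ranged from 0% (cHF-F vs cHF) to 1.75% (Krill-H vs cHF). Pooled over simulations it ranged from 0.611% (Cal-L vs Krill-L) to 55.9% (cHF vs STD), because single simulations called many genes together, and more than 5% of calls were false in 1 of 10 simulations for cHF vs STD and in between 0 (Cal-L vs Krill-L) and 3 (Krill-H vs cHF, Krill-L vs cHF and Krill-H vs Krill-L) for the others. A made list of 30 genes shifted by 0.3 was found in 10 of 10 simulations by all 3 list tests. Its genes were drawn at random, while genes of a written list may vary together, so this does not give the power for the written lists. The preset correlation also called between 5.9 (Krill-H vs cHF-F) and 12.2 (Krill-H vs cHF) unchanged lists per simulation, the estimated correlation between 0 and 0.8, and fry between 0 and 0.4.

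Genes named in the text follow a rule fixed in advance. It takes the 8 genes with the largest rise and the 8 with the largest fall past the threshold, or 6 of each for the 5 comparisons between supplemented diets, leaving out predicted and unnamed loci. It adds, from up to 6 lists called with the smallest p in a comparison, the 3 members of smallest p, and always considers Cpt1a, Cyp4a10, Acot1, Pdk4, Ehhadh, Fads2, Scd1 and Sqle. Some genes the rule gives are not reported here, and they are left out of the counts of gene values. Of the genes the rule gives, those that carry the account are printed. Genes named outside it are marked as chosen after their values were seen.

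The alternatives tried were no background correction, the log ratio of Feature Extraction, median centring in place of loess, Aquantile scaling, the Cy5 channel alone, the authors' value table, other probe filters, the mean of all probes of a gene, a trended and robust variance, array weights, only the compared groups in the model, the slide as a block, the replicate number as a block and leaving out each array in turn. Aquantile scaling and the trended and robust variance cannot change a list test. Both therefore kept every list call by construction and are included in the counts of settings. After the data were seen, 4 more were added. These left out the arrays labelled STD 8 and Cal-L 8, left out 4 arrays of unusual signal (STD 1, cHF 5, Krill-L 6 and Cal-L 4), left out Krill-H 1 for the lists of 3 of its comparisons, or used the mean of the pancreatic acinar list as a covariate. Correlations between comparisons that share a control were set beside 100 simulations of unchanged groups. Overlaps of calls were set beside the overlap of as many top genes by limma's statistic in those simulations and beside the calls with the cHF arrays split, 4 to each comparison, both added after the data were seen. For each comparison, 100 splits of its 16 arrays, the real one included, were fitted in the same way. Probes without any measurement above background were left out, and no other measurement was analysed here.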

Results

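Gene expression was measured in the whole small intestine of 48 male C57BL/6N mice, 24 weeks old, in 6 diet groups of 8. The series asks how different lipid forms of omega-3 fatty acids act on the mouse small intestine. STD was a low-fat chow with 3.5% fat by weight, and cHF was a high-fat diet with about 35% fat based on corn oil. In cHF-F, 15% of the lipids were replaced by a fish oil concentrate of triacylglycerols (52.5 g oil and about 31.5 g of the fatty acids EPA and DHA per kg of diet). Krill oil carries much of its EPA and DHA in phospholipids. Krill-H held it at the EPA and DHA content of cHF-F (31.5 g per kg), and Krill-L at the oil mass of cHF-F (52.5 g per kg, with 10.8 g EPA and DHA). Calanus oil comes from a copepod and is rich in wax esters, and Cal-L held 52.5 g of it per kg, with 5.846 g EPA and DHA. Mice ate these diets for 8 weeks after 1 week of adaptation.

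Each array compared 1 sample, in Cy5, with a common pool, in Cy3. The median net Cy5 intensity of an array ranged from 13 to 223 (median 29), that of Cy3 from 49.5 to 246, and between 39.2 and 79.9% of probes were well above background in Cy5. At most 2 spots of an array were saturated in Cy5. Arrays of the same diet correlated with a median r of 0.218 over genes, and arrays of different diets with 0.198. The highest r of any pair was 0.769, and no pair of arrays held matching values. The first principal component held 31.3% of the variance, of which the diet explained 9.19% and the slide 17.8%.

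Genes of fat metabolism on a pair of arrays lay far from the other arrays of their diet. Acot1, which splits acyl-CoA into free fatty acid and coenzyme A, had a log2 ratio to the pool of -0.02 on the array labelled STD 8, against -3.78 to -3.04 on the other 7 STD arrays. On the array labelled Cal-L 8 it was -3.36, against -0.84 to 0.64 on the other 7 Cal-L arrays. On a scale from 0 for the mean of STD arrays to 1 for the mean of high-fat arrays, over 50 genes, the array labelled STD 8 scored 0.906 and the array labelled Cal-L 8 scored -0.229. Other STD arrays scored between -0.144 and 0.22, and other high-fat arrays between 0.666 and 1.29. Both arrays kept their labels in every value below, so directions drawn from STD or Cal-L include them. Counts without both, on 46 arrays, are given beside them, as are printed genes and lists that then pass, no longer pass or move by over 1.5 times. That alternative was chosen after the data were seen and because of these values, so its p-values are not independent evidence.

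**Figure D1:**
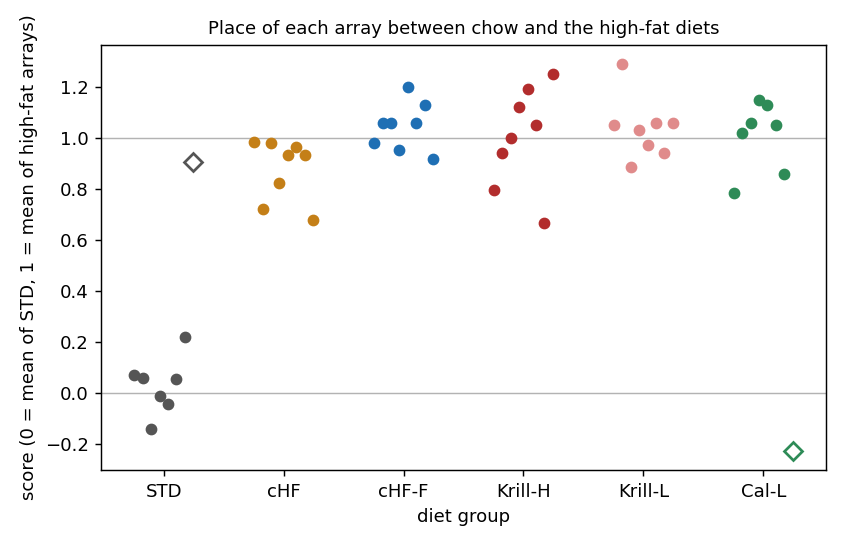
Score of each array on the scale between low-fat chow (0) and high-fat diets (1), over the 50 genes with the largest t between STD and the high-fat diets, by diet (horizontal axis). Circles are arrays, and open diamonds the arrays labelled STD 8 (0.906) and Cal-L 8 (-0.229), which were left out of building the scale along with the array scored.

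The comparison of cHF with STD asked what a high-fat diet changed in the intestine. Fat content, fat source and any other difference between the chow and the corn oil diet cannot be told apart in it. Gene lists of fatty acid oxidation, ketone bodies, and triglyceride resynthesis and chylomicrons were higher in cHF, while single genes rose and fell. Acot1 rose by 2.00 on the log2 scale (SE 0.403, n = 8 per diet, adjusted p = 0.00442, limma). Mfsd2a, a transporter of lysophosphatidylcholine, rose by 1.83 (SE 0.236), and Fabp1, a fatty acid binding protein of the absorptive cells, rose by 1.54 (SE 0.246). Limma called 186 of 23604 genes, 149 higher and 37 lower in cHF, and 172 with the slide as a block. At an unadjusted p under 0.05 there were 1643, or 6.96% of genes. Without any effect about 5% are expected, so a share under 5%, as in several comparisons below, holds no excess over chance.

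Besides Acot1, Mfsd2a and Fabp1, the named genes with the largest rises were Slc6a3, the dopamine transporter (1.92, SE 0.255), Dnah2, an axonemal dynein (1.72, SE 0.261), and Leap2, whose peptide blocks the ghrelin receptor (1.58, SE 0.24). Me1, which makes NADPH from malate (1.5, SE 0.295), and the small GTPase Rab30 (1.44, SE 0.285) followed, and a second Rab30 probe gave 0.29. The largest falls were in Mbl2, a lectin of innate immunity (-1.75, SE 0.383), and Cyp2c38 (-1.62, SE 0.302). Falls of between -1.23 and -1.21 were measured for Cyp3a16, Cyp2c55, Cyp3a11 and the glucose-sensing transporter Slc5a4a. Scd2, a stearoyl-CoA desaturase (-1.11, SE 0.182), and the glutathione transferase Gstm1 (-0.96, SE 0.184) also fell. Adjusted p for these 16 genes, Acot1, Mfsd2a and Fabp1 included, ranged from 8.33e-06 (Mfsd2a, higher on 6 of 6 slides) to 0.0188 (Cyp3a11, lower on 6 of 6 slides) in limma. Cyp4a10 (1.56, adjusted p = 0.0649), Cpt1a (0.40, 0.122), Pdk4 (0.77, 0.276) and Scd1 (-0.61, 0.174) did not pass.

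Fatty acid oxidation genes were higher in cHF as groups. Of 28 measured genes of peroxisomal oxidation, 4 rose and 0 fell over all genes (18 rose adjusted over the list alone, median 0.27, adjusted p = 0.0394 with an estimated correlation, higher on 5 of 6 slides). Of 27 of mitochondrial oxidation, 5 rose and 0 fell (13 over the list alone, median 0.27, adjusted p = 0.0394 with an estimated correlation, 5 of 6 slides). Examples from both lists were Acadl, the long-chain acyl-CoA dehydrogenase (1.15, SE 0.187), Acadvl (0.58, SE 0.129) and Hacl1, which shortens branched fatty acids (0.56, SE 0.12). Of 8 ketone body genes, 2 rose and 0 fell (adjusted over the list alone, 4 rose and 1 fell, median 0.19, adjusted p = 0.0394 with an estimated correlation, 6 of 6 slides). Of 24 genes of triglyceride resynthesis and chylomicrons, 9 rose and 0 fell (13 over the list alone, median 0.28, adjusted p = 0.0328 with an estimated correlation, 5 of 6 slides). Dgat2, which adds the last acyl chain of a triglyceride, rose by 0.96 (SE 0.17, higher on 6 of 6 slides). Of 30 targets of PPAR-alpha, the nuclear receptor of fatty acids, 7 rose and 0 fell (15 over the list alone, median 0.36), with adjusted p = 0.0537 with an estimated correlation and 0.0148 by fry. Creb3l3 (0.69) was among them. Slc27a2 (0.77), of the triglyceride and chylomicron list, and Acot4 (0.84), of the peroxisomal list, rose too. Under 15 other settings the calls with an estimated correlation held in 8 for peroxisomal oxidation (highest adjusted p 0.721), 7 for mitochondrial oxidation (0.693), 9 for ketone body genes and 10 for triglycerides and chylomicrons, while fry called all of these lists. Of 31 genes of xenobiotic metabolism, 1 rose and 2 fell (adjusted over the list alone, 5 rose and 7 fell, median -0.07, adjusted p = 0.808 with an estimated correlation), and without both doubted arrays 4 rose and 3 fell (median -0.02, adjusted p = 0.991 with an estimated correlation).

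Of 14 genes of enterocytes, the absorptive cells, 4 rose and 0 fell (adjusted over the list alone, 5 rose and 1 fell, median 0.13, mean 0.34, adjusted p = 0.137 with an estimated correlation and 0.0451 by fry, higher on 5 of 6 slides). The 4 were Fabp1, the retinol carrier Rbp2 (1.24), Apoa4 (1.22) and Fabp2 (0.83), and all but Rbp2 are also in the list of triglycerides and chylomicrons. Alpi (0.16), Sis (0.06) and Vil1 (-0.08) did not pass. Of 12 genes of the proximal small intestine, 2 rose and 0 fell, Fabp1 and Apoa4 (median 0.03, mean 0.24, adjusted p = 0.135 with an estimated correlation, higher on 5 of 6 slides). The enterocyte genes were named after their values were seen, except Fabp1. Of 15 smooth muscle genes, 1 fell and 0 rose (adjusted over the list alone, 8 fell, median -0.34, adjusted p = 0.137 with an estimated correlation, lower on 4 of 6 slides). The one was Actg2, the enteric smooth muscle actin (-0.92, SE 0.218). Genes of pancreatic acinar tissue, which lies against the duodenum, had a median of -2.15 between the diets (27 genes, 0 called, adjusted p = 0.214 with an estimated correlation). Their mean per array ranged from -3.96 to 1.86 over all diets. Leaving out the array labelled STD 8 alone raised the count of called genes from 186 to 287. Without both doubted arrays limma called 361 genes, 275 higher and 86 lower, which included all 186. Acot1 was then 2.41, and Cyp4a10 (2.00), Cpt1a (0.50), Pdk4 (0.92) and Scd1 (-0.69) passed, as did PPAR-alpha targets as a group (median 0.45, adjusted p = 0.00235 with an estimated correlation). From the authors' value table the count was 22, with 21 higher and 1 lower, against 149 and 37, and it was 306 with the log ratio of Feature Extraction, 19 with median centring and 118 with the compared diets alone in the model.

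The comparison of cHF-F with cHF asked what fish oil triacylglycerols changed on the high-fat background. No single gene passed, while PPAR-alpha targets were higher as a group and cholesterol synthesis genes lower, in calls that about as many settings lost as kept. Cyp4a10, which oxidises the far end of fatty acids, was 1.73 higher in log2 (SE 0.422, n = 8 per diet), and its relatives Cyp4a31 and Cyp4a32 were 1.62 (SE 0.383) and 0.96 (SE 0.244) higher. Limma called 0 genes, also with the slide as a block, and no other tool was run. At an unadjusted p under 0.05 there were 607 (2.57%), fewer than expected without any effect. Adjusted p was 1 for each named gene.

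Of 30 PPAR-alpha targets, 0 passed over all genes and 16 rose adjusted over the list alone (median 0.35, adjusted p = 0.0418 with an estimated correlation, higher on 6 of 6 slides). Acot1 was 1.11 higher (unadjusted p = 0.00864, limma), Decr2, a peroxisomal reductase of unsaturated fatty acids, 0.43 (0.000399) and Acad11 0.36 (0.00122). Mitochondrial oxidation genes had a median of 0.24 (12 of 27 rose adjusted over the list alone, adjusted p = 0.0584 with an estimated correlation) and peroxisomal ones 0.19 (7 of 28; 0.156). Of 28 cholesterol synthesis genes, 0 passed over all genes and 1 fell adjusted over the list alone (median -0.14, adjusted p = 0.0316 with an estimated correlation, lower on 6 of 6 slides). Fdft1, squalene synthase, was -0.37 (SE 0.109), Insig1, which holds back sterol synthesis, was -0.29, and Pmvk was -0.23. Of 29 genes of the NRF2 and glutathione response to oxidants, 0 passed over all genes and 1 rose adjusted over the list alone (median 0.12, adjusted p = 0.0418 with an estimated correlation, higher on 6 of 6 slides). Acinar genes had a median of 1.79 in the same comparison (adjusted p = 0.447 with an estimated correlation). With both doubted arrays left out, which are in neither diet but add to the shared spread, 2 genes passed, Cyp4a10 and Cyp4a31, and mitochondrial and peroxisomal oxidation passed as groups with an estimated correlation. Under 15 other settings the calls with an estimated correlation held in 8 for PPAR-alpha targets (highest adjusted p 0.79), 8 for cholesterol synthesis (0.995) and 6 for the NRF2 list (0.995), and fry called 0 lists. Modelling the compared diets alone called 4 genes, Cyp4a10, Cyp4a31, Cyp4a32 and Me1, of which Me1 was chosen after its values were seen.

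The comparison of Krill-H with cHF asked the same of krill oil at the higher dose. Cyp4a10 and Cyp4a31 had the largest rises. The xenobiotic and NRF2 lists were higher as groups, and the antimicrobial and Paneth cell lists, which share genes, lower. Cyp4a10 rose by 2.97 on the log2 scale (SE 0.422, n = 8 per diet, adjusted p = 3.93e-05, limma), Cyp4a31 by 2.83 (SE 0.383) and Cyp4a32 by 1.84 (SE 0.244), each a near copy of the others. Lyz1, the lysozyme of Paneth cells, fell by 0.74 (SE 0.116, adjusted p = 0.000232). Limma called 62 genes, 53 higher and 9 lower, and 54 with the slide as a block, with 753 (3.19%) at an unadjusted p under 0.05.

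The other large rises were in Cyp2c38 (1.86, SE 0.302), Me1 (1.43, SE 0.295), the proton channel Otop2 (1.34, SE 0.249), Hsd17b11, a dehydrogenase on lipid droplets (1.31, SE 0.255), and Tm4sf4 (1.15, SE 0.251). Falls were measured for Mfsd2a (-1.07, SE 0.236), the Paneth cell defensin Defa21 (-0.79, SE 0.183), Insig1 (-0.60, SE 0.126), Krtap4-8 (-0.51, SE 0.109) and Spns3 (-0.43, SE 0.0868). Adjusted p for these 10 genes ranged from 0.000488 (Cyp2c38) to 0.0362 (Defa21) in limma. Acot1 (1.32, adjusted p = 0.304) and Scd1 (0.69, 0.132) did not pass.

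Of 30 PPAR-alpha targets, 10 rose and 0 fell (adjusted over the list alone, 22 rose and 1 fell, median 0.53, adjusted p = 2e-04 with an estimated correlation, higher on 6 of 6 slides). Of 28 peroxisomal oxidation genes, 6 rose and 0 fell (13 and 1 over the list alone, median 0.32, adjusted p = 0.0055 with an estimated correlation), with Ehhadh (0.56, SE 0.0929), Acaa1b (0.76, SE 0.135) and Decr2 (0.53, SE 0.114) among them. Of 27 mitochondrial oxidation genes, 3 rose and 0 fell (13 and 1 over the list alone, median 0.26, adjusted p = 0.00474 with an estimated correlation), namely Acad11 (0.57), Slc22a5, the carnitine carrier (0.71), and Etfb (0.43). Both lists were higher on 5 of 6 slides. Of 31 genes of xenobiotic metabolism, 3 rose and 0 fell (11 over the list alone, median 0.35, adjusted p = 0.00386 with an estimated correlation, 5 of 6 slides), among them Cyp2c65 (1.13, SE 0.149) and Cyp2c66 (1.13, SE 0.16). Of 29 genes of the NRF2 and glutathione response, 6 rose and 0 fell (13 and 1 over the list alone, median 0.23, adjusted p = 1.15e-05 with an estimated correlation, 6 of 6 slides). These included Akr1b8, an aldehyde reductase (1.11, SE 0.186), Ephx1, the microsomal epoxide hydrolase (0.89, SE 0.146, second probe 0.21), and Gsta2 (0.81, SE 0.162).

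Of 28 cholesterol synthesis genes, 1 fell and 0 rose (9 fell adjusted over the list alone, median -0.14, adjusted p = 0.00053 with an estimated correlation, lower on 6 of 6 slides). Sqle (-0.45, adjusted p = 0.318) and Hmgcs1 (-0.42, 0.0752) did not pass over all genes. Of 13 sterol transport genes, 1 rose and 0 fell (2 over the list alone, median 0.10, adjusted p = 0.0229 with an estimated correlation). Of 14 antimicrobial genes, 2 fell and 0 rose (5 over the list alone, median -0.48, adjusted p = 0.00386 with an estimated correlation, lower on 5 of 6 slides), and of 8 Paneth cell genes, 2 fell and 0 rose (4 over the list alone, median -0.34; 0.00646, 5 of 6 slides). The fallen genes were Lyz1 and Defa21 in both lists, so the calls of these lists are not separate findings. Of 8 mast cell genes, 0 passed over all genes and 3 rose adjusted over the list alone (median 0.32, adjusted p = 0.0138 with an estimated correlation, 6 of 6 slides). Without Krill-H 1 the median was 0.18 for mast cell genes (adjusted p = 0.0447 with an estimated correlation) and -0.57 for Paneth cell genes (0.00292). Acinar genes had a median of 1.43 (adjusted p = 0.37 with an estimated correlation) and smooth muscle genes one of 0.26 (0.157).

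The count for Krill-H depended on single arrays, with 40 genes without Krill-H 8 and 110 without Krill-H 7. Without both doubted arrays it was 112, 95 higher and 17 lower, which included all 62, and Acot1, Scd1 and Hmgcs1 passed. Array weights gave 162 and the compared diets alone 38. The list calls with an estimated correlation held in 9 (sterol transport) to 15 (PPAR-alpha targets) of 15 other settings, and fry called 9 lists, all of these but sterol transport. The split of 53 higher and 9 lower was 79 and 26 with the log ratio of Feature Extraction, 5 and 0 with median centring and 8 and 0 from the authors' value table.

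**Figure D2:**
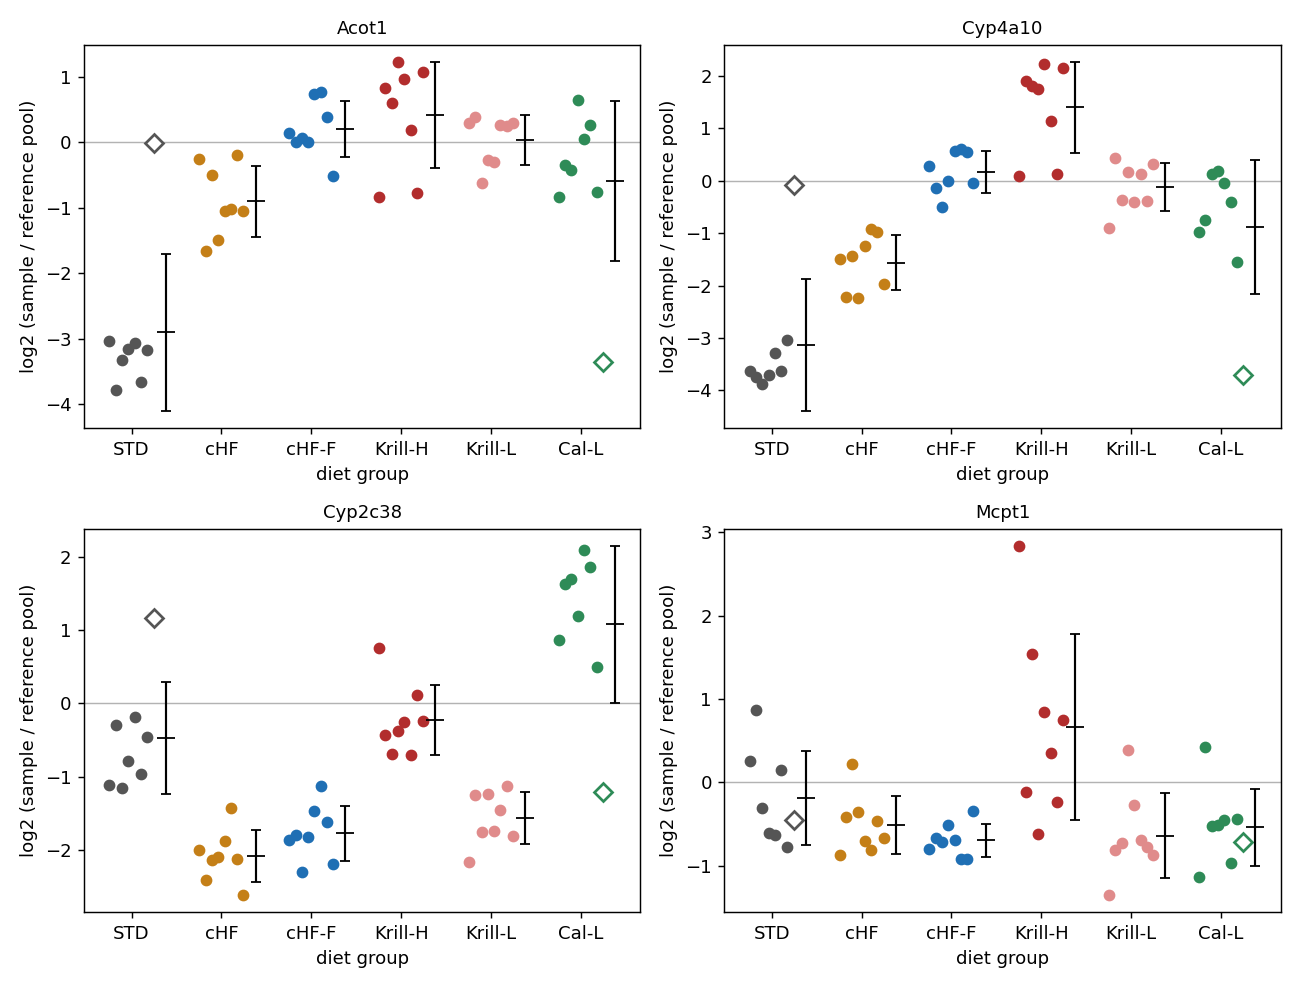
Log2 ratio to the reference pool of single genes on each array (vertical axes) by diet (horizontal axes). Circles are arrays, open diamonds the arrays labelled STD 8 and Cal-L 8, and black marks with bars are the mean and SD of all 8 arrays of a diet. Cyp4a10 ranged from 0.10 to 2.22 on Krill-H arrays and from -2.25 to -0.92 on cHF arrays, and Cyp2c38 from 0.51 to 2.1 on the other 7 Cal-L arrays.

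The comparison of Krill-L with cHF asked the same of krill oil at the oil mass of the fish oil diet. No gene passed and no list was called with an estimated correlation. Cyp4a10 was 1.44 higher in log2 (SE 0.422, n = 8 per diet), Cyp4a31 1.26 (SE 0.383) and Cyp4a32 0.85 (SE 0.244). Limma called 0 genes, also with the slide as a block, with 416 (1.76%) at an unadjusted p under 0.05. Of 30 PPAR-alpha targets, 8 rose adjusted over the list alone (median 0.26, adjusted p = 0.105 with an estimated correlation, higher on 6 of 6 slides), and of 31 xenobiotic genes 4 did (median 0.22; 0.115), with Cyp3a11 at 0.86 (SE 0.284). Mitochondrial oxidation genes, with Acad11 at 0.38, had a median of 0.18 (1 of 27 over the list alone, adjusted p = 0.124 with an estimated correlation). Cholesterol synthesis genes, with Sqle at -0.45, had one of -0.10 (adjusted p = 0.0878 with an estimated correlation, lower on 6 of 6 slides). Acinar genes had a median of 1.40 (adjusted p = 0.433 with an estimated correlation). With both doubted arrays left out limma still called 0 genes, with 446 at an unadjusted p under 0.05, while PPAR-alpha targets, mitochondrial oxidation, cholesterol synthesis and xenobiotic metabolism passed as groups with an estimated correlation. Modelling the compared diets alone called 2 genes, Cyp4a10 and Cyp4a31, and the log ratio of Feature Extraction called 1 feature, at 58197113 to 58200614 on chromosome 9 of mm9, chosen after its values were seen.

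The comparison of Cal-L with cHF asked the same of Calanus oil. Single cytochrome P450 genes of the Cyp2b, Cyp2c and Cyp3a families and 2 glutathione transferase genes rose, and no gene fell. Probes within a family may cross-hybridise, so these genes may not be separate findings. Cyp2c38 rose by 3.17 on the log2 scale (SE 0.302, n = 8 per diet, adjusted p = 2.08e-09, limma), Cyp2c55 by 1.92 (SE 0.262) and Cyp3a11 by 1.82 (SE 0.284), each higher on 6 of 6 slides. Limma called 21 genes, 21 higher and 0 lower, and 22 with the slide as a block, with 1473 (6.24%) at an unadjusted p under 0.05. Cyp3a16 (1.73, SE 0.258), Cyp2b10, a target of the xenobiotic receptor CAR (1.73, SE 0.243), Cyp3a41b (1.39, SE 0.215), Cyp2b9 (1.32, SE 0.231), Cyp2c29 (1.31, SE 0.161) and Cyp2c65 (1.10, SE 0.149) rose as well. So did the glutathione transferases Gstm1 (1.51, SE 0.184) and Gstm3 (1.13, SE 0.168) and the epoxide hydrolase Ephx1 (1.08, SE 0.146, second probe 0.38). Adjusted p for these 9 genes ranged from 1.45e-06 (Gstm1 and Cyp2c29) to 0.00112 (Cyp2b9) in limma.

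Of 31 xenobiotic genes, 6 rose and 0 fell with Calanus oil (9 over the list alone, median 0.30, higher on 6 of 6 slides), with adjusted p = 0.198 with an estimated correlation and 0.00484 by fry, which does not compare the list with other genes. Of 29 NRF2 and glutathione genes, 3 rose and 0 fell (11 over the list alone, median 0.13, 6 of 6 slides), with adjusted p = 0.0652 with an estimated correlation and 0.000209 by fry. The fatty acid genes Cyp4a10 (0.68, adjusted p = 0.646) and Acot1 (0.31, 0.772) did not pass, nor without both doubted arrays, where they were 1.08 (adjusted p = 0.191) and 0.70 (0.515). T and intraepithelial lymphocyte genes, with the chemokine Ccl5 at -0.40, had a median of -0.14 (adjusted p = 0.283 with an estimated correlation), and acinar genes had one of 1.88 (0.784). Without both doubted arrays the count was 33, all higher and including all 21. Xenobiotic and NRF2 genes then passed as groups with an estimated correlation. With all arrays the count was 34 with array weights and 2, Cyp2c38 and Ephx1, with the compared diets alone in the model. With median centring the median of all genes lay at 0.13 in this comparison and at 0.12 in Cal-L against Krill-L, against 0.06 in both here, so values with that scaling are relative to those shifts.

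**Figure D3:**
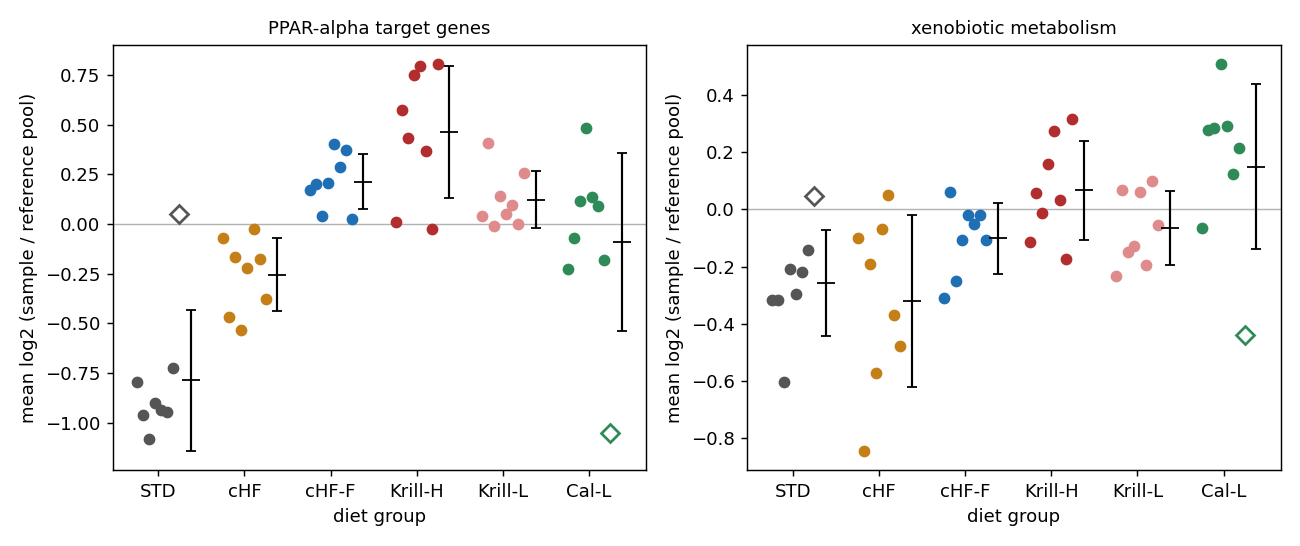
Mean log2 ratio to the reference pool of the genes of single lists on each array (vertical axes) by diet (horizontal axes). Circles are arrays, open diamonds the arrays labelled STD 8 and Cal-L 8, and black marks with bars are the mean and SD of all 8 arrays. PPAR-alpha targets had a mean of -0.79 on STD and 0.46 on Krill-H arrays, and the array labelled STD 8 lay at 0.05.

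The comparison of Krill-H with cHF-F, at the same EPA and DHA content, asked whether the lipid form made a difference. The labels give no oil mass for Krill-H, but Krill-L held 52.5 g krill oil for 10.8 g EPA and DHA. Krill-H, at 31.5 g EPA and DHA, therefore held more oil than the 52.5 g of cHF-F. Lipid form and oil mass cannot be told apart in this comparison. The NRF2 list and the mast cell list were higher with krill oil, and no single gene passed. Among the mast cell protease genes, Mcpt1 was at 1.36 in log2 (SE 0.292, n = 8 per diet, adjusted p = 0.158, limma), Mcpt2 at 1.29 (SE 0.316) and Mcpt4 at 1.23 (SE 0.298). Limma called 0 genes, also with the slide as a block, with 707 (3%) at an unadjusted p under 0.05 and a lowest adjusted p of 0.1. Of 8 mast cell genes, 3 rose adjusted over the list alone (median 0.27, adjusted p = 0.0276 with an estimated correlation, higher on 6 of 6 slides), and without Krill-H 1 the median was 0.14 (adjusted p = 0.0477 with an estimated correlation). That array had a mean of mast cell genes of 1.35, against -0.16 to 0.69 on the other 7 Krill-H arrays. Its means of goblet cell genes (0.93, others -0.22 to 0.22), tuft cell genes (0.62, -0.13 to 0.22) and eosinophil and neutrophil genes (0.50, -0.08 to 0.10) also lay above those of the other 7. Of 29 NRF2 genes, 2 rose adjusted over the list alone (median 0.13, adjusted p = 0.0303 with an estimated correlation, 6 of 6 slides). These calls held in 11 and 8 of 15 other settings, and fry called 0 lists. Ephx1 was 0.57 higher (adjusted p = 0.427) and Akr1b8 0.59 (1). The difference in Cyp4a10 was 1.23 (95% interval 0.39 to 2.08, adjusted p = 1), that in Cyp4a31 1.22 (0.45 to 1.99) and that in Ehhadh 0.44 (0.25 to 0.62, adjusted p = 0.158). PPAR-alpha targets had a median of 0.17 (5 of 30 rose adjusted over the list alone, adjusted p = 0.252 with an estimated correlation; 0.27 and 0.0964 without Krill-H 1). Antimicrobial genes had one of -0.36 (adjusted over the list alone, 1 rose and 6 fell, adjusted p = 0.173 with an estimated correlation). Scd1 was 0.73 higher (adjusted p = 0.427) and Cyp2c65 0.60 (0.385). These intervals leave room for a difference between the diets, and a missed threshold does not show that they act alike.

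The count of 0 rested on single arrays, since limma called 2 genes without Krill-H 7, 1 without Krill-H 1 and 1 without cHF-F 1. With both doubted arrays left out it called 7, with Cyp4a31, Scd1 and Cyp2c38 among 3 higher and Lyz1 and Mfsd2a among 4 lower, and array weights also called 7. The log ratio of Feature Extraction and the compared diets alone each called 1, Cyp2c38, which was 1.55 higher (adjusted p = 0.1). Cyp2c38, Lyz1 and Mfsd2a were named here after their values were seen.

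The comparison of Krill-L with cHF-F set the same oil mass of both oils side by side, at 10.8 and 31.5 g EPA and DHA per kg. The plasma cell list was lower in Krill-L than in cHF-F. Its mean log2 ratio to the pool was 0.16 in cHF-F, -0.04 in cHF and -0.11 in Krill-L, so the difference cannot be credited to krill oil alone. Of 9 plasma cell genes, 0 passed over all genes and 0 adjusted over the list alone, while the list as a group was lower (median -0.26, adjusted p = 0.0116 with an estimated correlation, lower on 6 of 6 slides). The call held in 10 of 15 other settings, and fry called 0 lists. T and intraepithelial lymphocyte genes had a median of -0.13 (0 of 16 called, adjusted p = 0.625 with an estimated correlation, lower on 6 of 6 slides) and B cell genes one of -0.11 (0 of 13; 0.954, lower on 4 of 6). Mzb1, a chaperone of antibody secretion, was -0.37 (SE 0.146, n = 8 per diet), Tnfrsf17, the plasma cell receptor BCMA, -0.28 (SE 0.114) and Txndc5 -0.25 (SE 0.108), each at an adjusted p of 1 in limma. Limma called 0 genes, also with the slide as a block, with 220 (0.932%) at an unadjusted p under 0.05, and 0 without both doubted arrays, with 208.

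The comparison of Cal-L with cHF-F set both oils side by side at the same mass, at 5.846 and 31.5 g EPA and DHA per kg. Single P450 genes of the Cyp2b, Cyp2c and Cyp3a families rose with Calanus oil, while the xenobiotic list was not called as a group. Cyp2c38 was 2.86 higher in log2 (SE 0.302, n = 8 per diet, adjusted p = 5.49e-08, limma), Cyp2c55 1.49 (SE 0.262), Cyp2b10 1.32 (SE 0.243), Cyp2c29 1.11 (SE 0.161), Cyp2b9 1.08 (SE 0.231, adjusted p = 0.049) and Cyp3a41b 1.03 (SE 0.215). Dnase1, a secreted nuclease, fell by 0.95 (SE 0.162, adjusted p = 0.00241, lower on 6 of 6 slides). Limma called 13 genes, 12 higher and 1 lower, and 8 with the slide as a block, with 1510 (6.4%) at an unadjusted p under 0.05. Of 31 xenobiotic genes, 3 rose and 0 fell (7 over the list alone, median 0.08, adjusted p = 0.577 with an estimated correlation). Enterocyte genes had a median of -0.19 (3 of 14 fell adjusted over the list alone, adjusted p = 0.16 with an estimated correlation), with Apoa1 at -0.45, Fabp2 at -0.44 and Treh, the enzyme of trehalose digestion, at -0.36. PPAR-alpha targets had one of -0.22 (adjusted p = 0.23 with an estimated correlation), with Cyp4a10 at -1.06 (adjusted p = 0.751). The count was 7 without Cal-L 2 and 8 without Cal-L 3 or Cal-L 5. It was 2 higher and 0 lower from the authors' value table, 22 and 2 with array weights, and 8 both with the compared diets alone and without the 4 arrays of unusual signal. Without both doubted arrays it was 19, 18 higher and 1 lower, and included all 13. Fabp2 was then at -0.26, Cyp4a10 at -0.66, and the medians at -0.12 for PPAR-alpha targets and 0.16 for xenobiotic genes.

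The comparison of Krill-H with Krill-L asked what the dose of krill oil changed, from 10.8 to 31.5 g EPA and DHA per kg. The NRF2 and mast cell lists were higher at the higher dose, and no single gene passed. Of 29 NRF2 genes, 8 rose adjusted over the list alone (median 0.24, adjusted p = 0.000591 with an estimated correlation, higher on 6 of 6 slides), with Akr1b8 at 0.81 (SE 0.186, n = 8 per diet), Ephx1 at 0.57 (SE 0.146) and Gsr, glutathione reductase, at 0.47 (SE 0.124). Of 8 mast cell genes, 3 rose adjusted over the list alone (median 0.20, adjusted p = 0.00687 with an estimated correlation, 6 of 6 slides; 0.12 and 0.0299 without Krill-H 1), with Mcpt4 at 1.39 (SE 0.298), Mcpt1 at 1.31 (SE 0.292) and Mcpt2 at 1.31 (SE 0.316). Cyp4a31 was 1.58 higher (SE 0.383, adjusted p = 0.288, limma), Cyp4a10 1.52 (SE 0.422) and Cyp4a32 0.98 (SE 0.244), and PPAR-alpha targets had a median of 0.25 (6 rose and 1 fell adjusted over the list alone, adjusted p = 0.131 with an estimated correlation; 0.30 and 0.0299 without Krill-H 1). Limma called 0 genes, also with the slide as a block, with 539 (2.28%) at an unadjusted p under 0.05. It called 3 without Krill-H 4, 2 without Krill-H 1, 11 from the Cy5 channel alone, 6 with array weights and 1 with the compared diets alone (Cyp2c38, chosen after its values were seen). Both list calls held in 12 of 15 other settings, and fry called the NRF2 list only. With both doubted arrays left out it called 7, 6 higher and 1 lower, with Cyp4a31, Cyp4a32 and Cyp4a10 among the higher, and PPAR-alpha targets passed as a group with an estimated correlation.

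The comparison of Cal-L with Krill-L set both oils side by side at the same mass, at 5.846 and 10.8 g EPA and DHA per kg. Single genes rose with Calanus oil, among them Cyp2c and Cyp2b genes, while the xenobiotic list was not called as a group (31 genes, 3 rose and 0 fell, 6 over the list alone, median 0.08, adjusted p = 0.789 with an estimated correlation). Cyp2c38 was 2.65 higher in log2 (SE 0.302, n = 8 per diet, adjusted p = 5.23e-07, limma), Cyp2c55 1.42 (SE 0.262), Gstm1 1.29 (SE 0.184), Cyp2b10 1.19 (SE 0.243), Cyp2c29 1.04 (SE 0.161) and Mt2, a metallothionein that binds zinc, 1.19 (SE 0.247, adjusted p = 0.0336). Dnase1 fell by 0.76 (SE 0.162, adjusted p = 0.0387, lower on 6 of 6 slides). Limma called 15 genes, 14 higher and 1 lower, and 13 with the slide as a block, with 2323 (9.84%) at an unadjusted p under 0.05. Of 29 NRF2 genes, 3 rose and 0 fell (adjusted over the list alone, 4 rose and 1 fell, median 0.16, adjusted p = 0.329 with an estimated correlation and 0.018 by fry, 6 of 6 slides). Of 35 cell cycle genes, 0 passed over all genes and 15 rose adjusted over the list alone (median 0.19, adjusted p = 0.282 with an estimated correlation and 0.018 by fry, 6 of 6 slides), with Rrm2 at 0.46 (SE 0.12) and Tk1 at 0.26 (SE 0.0749). Enterocyte genes had a median of -0.29 (2 of 14 fell adjusted over the list alone, adjusted p = 0.259 with an estimated correlation), and Cd36, a fatty acid carrier, was -0.62 (adjusted p = 0.263) and Treh -0.37 (0.341). The count was 8 without Cal-L 4 and 9 without Krill-L 3. It was 8 with median centring, 5 from the authors' value table, 6 with the compared diets alone and 5 without the 4 arrays of unusual signal. Without both doubted arrays it was 20, of which 13 were among the 15. Mt2 no longer passed then (1.12, adjusted p = 0.0806), and enterocyte genes had a median of -0.18.

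Krill-H, cHF-F, Krill-L and Cal-L were all compared with the same cHF arrays, so their changes are related even without an effect. Over all genes, which are not independent replicates, the changes of Krill-H and cHF-F correlated with r = 0.598, against 0.495 in 100 simulations with no effect, and with -0.04 and 0.25 when the cHF arrays were split between the comparisons. For Krill-H and Krill-L r was 0.651 against 0.484 (0.02 and 0.19 on split arrays), for cHF-F and Krill-L 0.715 against 0.492 (0.22 and 0.09) and for cHF-F and Cal-L 0.539 against 0.452 (0.155 and 0.13). For Krill-H and Cal-L it lay below the simulated one, at 0.434 against 0.509 (-0.05 and 0.16). The covariance exceeded the simulated one by 0.00136, 0.00217, 0.00357, 0.00475 and 0.000428 in this order. The changes in cHF against STD correlated with those in Cal-L at -0.6, against -0.474 with no effect (-0.18 and -0.37 on split arrays), with a covariance that differed from the simulated one by -0.0118. With those in Krill-H they correlated at -0.409, against -0.471 (-0.05 and -0.03), and the covariance differed by -0.00118. STD and Cal-L hold the doubted arrays.

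Of the 62 genes called in Krill-H, 62 had the same direction in cHF-F, 61 in Krill-L and 59 in Cal-L, where simulations with no effect gave 85.6%, 84.7% and 83.8%. Genes called higher in both Krill-H and Cal-L numbered 6. Independent lists give 0.0472, while lists of as many top genes in the simulations shared 2.44 on average and up to 10, and 3 and 5 genes were shared on split arrays. In Cal-L, 9 genes were higher against cHF that were lower in cHF against STD. Independent lists give 0.0329, the simulations gave 1.75 on average and up to 8, and split arrays gave 1 and 3. In Krill-H 4 genes were, against 0.0831, 3.29 on average and up to 12, and 1 on either split. Genes lower in Krill-H and higher in cHF against STD numbered 2, against 0.0568, 2.1 on average and up to 6, and 0 on either split. The simulations leave out the effects and independent lists leave out the shared arrays, so an excess over either does not show a shared effect.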

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

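The tests of what may lie behind the arrays labelled STD 8 and Cal-L 8, including the score of -0.229 used in one of them, were all chosen after the values were seen. Named genes were checked for an array that stood apart only where called in a comparison, and only in both diets compared. Lists were checked in the same way where called at the preset correlation with an unadjusted p under 0.05 at an estimated correlation. Other diets were not checked, such as Cal-L for Acot1, where the array labelled Cal-L 8 was at -3.36. The checked values made 242 sets of 8 in all. In 27 of them the gap between the highest or lowest array and its nearest neighbour exceeded Dixon's 95% critical share of the whole range for 8 values. Chance alone gives such a gap in about 5% of sets.

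Of the 27, 13 were on the array labelled STD 8, on the side of cHF for every one but Cyp2c38. Its log2 ratios to the pool were -0.0193 for Acot1 (other 7 STD arrays -3.78 to -3.04), -0.238 for Slc6a3 (-2.17 to -1.4), -0.138 for Mfsd2a (-1.92 to -1.33), -0.174 for Dnah2 (-2.23 to -1.32) and 0.101 for Fabp1 (-1.8 to -1.44). They were 0.0714 for Me1 (-3.1 to -1.62), 0.0584 for Rab30 (-2.37 to -1.23), 0.176 for Acadl (-1.75 to -1.1) and -0.118 for Acadvl (-1.13 to -0.776). Scd2 was at -0.125 (0.745 to 1.35), the mitochondrial oxidation list at 0.0292 (-0.63 to -0.447) and the PPAR-alpha list at 0.0497 (-1.08 to -0.724). Cyp2c38, the gene of the largest rise with Calanus oil, was at 1.18 (-1.16 to -0.178).

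The array labelled Cal-L 8 stood apart in 5 sets. Cyp2b10 was at -1.23 (other 7 Cal-L arrays 0.688 to 1.25), Cyp2b9 at -0.804 (0.628 to 1.9), the mitochondrial oxidation list at -0.667 (-0.112 to 0.172), the PPAR-alpha list at -1.05 (-0.229 to 0.481) and the list of triglyceride resynthesis and chylomicrons at -0.724 (-0.139 to 0.156).

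An exchange of the samples behind both arrays is one candidate explanation, and they lay next to each other on slide 6. On the first scale tried, from the other high-fat diets to Calanus oil over 50 genes, the array labelled STD 8 scored 0.559, inside the range of the other Cal-L arrays (0.449 to 1.55) but also of the other STD arrays (-0.0195 to 0.707), which decided nothing. A second scale was added for that reason, over the 33 genes called between Cal-L and cHF without both arrays, and there it scored 0.799, inside the other Cal-L arrays (0.549 to 1.44) and above the other STD arrays (-0.0649 to 0.483), with the array labelled Cal-L 8 at 0.161, which is consistent with an exchange, although other high-fat arrays reached 0.75. A mixture of both RNAs is argued against by the score of -0.229 of the array labelled Cal-L 8 between chow and high fat, below the other STD arrays (-0.144 to 0.22), and weak signal by 49.8% of probes above background on the array labelled STD 8, within the range of the other arrays. A wrong label on 1 array alone would leave the other unexplained, since both lay outside the range of their own diet, while separate errors on both stay open, no biological explanation was tested and the labels were kept.

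The other 9 sets were on 8 different arrays. Hacl1 was at -1.24 on STD 4 (others -0.64 to -0.186) and Cyp3a11 at -3.7 on cHF 2 (-1.76 to -0.193). Akr1b8 was at 0.0403 on cHF 8 (-0.849 to -0.471) and Me1 at -0.297 on Krill-H 7 (0.728 to 1.33). Cyp2b9 was at -0.587 on cHF-F 3 (-0.298 to -0.107) and Cyp3a41b at 2.08 on Cal-L 4 (0.36 to 0.896). The sterol transport list was at 0.323 on Cal-L 4 (-0.153 to 0.0262), the goblet cell list at 0.934 on Krill-H 1 (-0.217 to 0.222) and the list of peptide and amino acid uptake at 0.0516 on cHF-F 2 (-0.0641 to -0.0185).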

How the results depend on the processing

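The alternatives that left out chosen arrays or used the acinar mean as a covariate were picked after seeing the data, and the others were planned. Gene and list values were not recomputed without single arrays, apart from mast cell genes and lists without Krill-H 1, without the 4 arrays of unusual signal or with the acinar covariate. Of the 134 gene values, 0 changed direction under the other alternatives, and under the settings planned in advance 1694 values kept their side of the threshold, 152 lost it and 25 gained it. Of 156 lists called at the preset correlation, which called too many lists on simulated data, 1979 values kept that call, 199 lost it and 6 reversed. Of the 10 counts of called genes, 113 planned values stayed within 1.5 times and 27 did not. The 22 lists called with an estimated correlation held in 230 of 330 values, each in between 6 and 15 of 15 settings, and PPAR-alpha targets in Krill-H vs cHF in 15 (highest adjusted p 0.0327). Aquantile and the trended and robust variance leave every list test as it is. The kept values of both kinds of list call therefore include theirs by construction. Signal limits what dim probes show, since a median of 51.0% of probes per array was above background. The cause was not tested unless stated.

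With the log ratio of Feature Extraction, counts were 306 (cHF vs STD), 105 (Krill-H vs cHF), 1 (Krill-L vs cHF) and 1 (Krill-H vs cHF-F, Cyp2c38). With median centring they were 19 (cHF vs STD), 5 (Krill-H vs cHF: Cyp2c38, Otop2, Cyp4a10, Cyp4a31 and Cyp4a32) and 8 (Cal-L vs Krill-L). From the authors' value table they were 22 (cHF vs STD), 8 (Krill-H vs cHF), 2 (Cal-L vs cHF-F, Cyp2c38 and Cyp2c39) and 5 (Cal-L vs Krill-L: Cyp2c38, Cyp2c39, Gstm1, AI606402 and an unnamed probe), and from Cy5 alone 11 (Krill-H vs Krill-L). Genes that such small counts name were chosen after their values were seen.

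The direction given by camera, which is relative to other genes, reversed for some lists. With median centring these were triglycerides and chylomicrons (median 0.169) and peptide and amino acid uptake (0.179) in Cal-L vs cHF. The respiratory chain in Krill-H vs Krill-L (-0.0238) and peptide and amino acid uptake in Cal-L vs Krill-L (0.229) reversed there as well. From the authors' value table the first pair reversed, with medians of 0.114 and 0.122. The median of all genes in Cal-L vs cHF was 0.0951 in that table and 0.128 with median centring, so these medians are relative to that shift. No direction is printed for these lists in the report.

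The slide as a block gave 8 genes in Cal-L vs cHF-F. Array weights gave 162 (Krill-H vs cHF), 34 (Cal-L vs cHF), 7 (Krill-H vs cHF-F), 24 (Cal-L vs cHF-F) and 6 (Krill-H vs Krill-L). Modelling only the compared diets, with fewer arrays to estimate the spread, gave 118 (cHF vs STD), 4 (cHF-F vs cHF), 38 (Krill-H vs cHF), 2 (Krill-L vs cHF), 2 (Cal-L vs cHF: Cyp2c38, Ephx1), 1 (Krill-H vs cHF-F: Cyp2c38), 8 (Cal-L vs cHF-F), 1 (Krill-H vs Krill-L: Cyp2c38) and 6 (Cal-L vs Krill-L).

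Without the arrays labelled STD 8 and Cal-L 8 counts were 361 (cHF vs STD), 2 (cHF-F vs cHF), 112 (Krill-H vs cHF), 33 (Cal-L vs cHF), 7 (Krill-H vs cHF-F) and 7 (Krill-H vs Krill-L). Without the 4 arrays of unusual signal they were 8 (Cal-L vs cHF-F) and 5 (Cal-L vs Krill-L: Cyp2c29, Cyp2c38, Cyp2c39, Cyb5a and Gstm1). The acinar covariate moved no count by over 1.5 times, and Aquantile leaves ratios as they are by construction.

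Leaving out each array in turn, counts ranged from 140 (without STD 3) to 287 (without STD 8) in cHF vs STD, 40 (without Krill-H 8) to 110 (without Krill-H 7) in Krill-H vs cHF, 20 (without cHF 2) to 31 (without Cal-L 8) in Cal-L vs cHF and 0 to 2 (without Krill-H 7; 1 without Krill-H 1 or cHF-F 1) in Krill-H vs cHF-F. They ranged from 7 (without Cal-L 2; 8 without Cal-L 3 or 5) to 18 (without Cal-L 8) in Cal-L vs cHF-F, 0 to 3 (without Krill-H 4; 2 without Krill-H 1) in Krill-H vs Krill-L and 8 (without Cal-L 4; 9 without Krill-L 3) to 18 (without Cal-L 8) in Cal-L vs Krill-L. They stayed at 0 in the other 3 comparisons.

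The correlations showed no clear pairing by replicate number. Between 1 and 5 of 8 same-numbered pairs correlated over 0.1, and an array correlated best with its own number in 0 to 3 of 8 cases. The median r of same-numbered pairs ran from -0.025 (Krill-H vs Krill-L, other pairs -0.0083) to 0.2 (Cal-L vs cHF-F, other pairs 0.045). Same-numbered arrays shared a slide in 4 (cHF vs STD) to 7 (Krill-L vs cHF and Cal-L vs Krill-L) of 8 pairs, so number and slide overlap. With the replicate number as a block the counts were 177, 0, 68, 0, 23, 0, 0, 11, 0 and 15, in the order of the report.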

Other observations

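The tests on mast cell and acinar genes, with the median ratio of 0.771 and the others printed for them, were chosen after the result was seen, while the splits of the samples were planned. Lists of hormone cells and goblet cells were not called between the chow and the high-fat diet with an estimated correlation, while fry gave an adjusted p under 0.05 for each. Of 15 gut peptide hormone genes, 1 rose and 0 fell in cHF vs STD (adjusted over the list alone, 3 rose and 1 fell; median 0.15; adjusted p = 0.0451 by fry in limma and 0.135 with an estimated correlation). Of 16 enteroendocrine genes, 1 rose and 0 fell (3 over the list alone; median 0.13; 0.0451 by fry and adjusted p = 0.124 with an estimated correlation). Of 12 goblet cell genes, which make the mucus, 0 passed over all genes or over the list alone (median -0.24; 0.0451 by fry and adjusted p = 0.113 with an estimated correlation). These lists stood apart from 0 in fry but were not shown to differ from other genes.

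Immune gene groups gave values that did not pass. Of 33 interferon response genes, 0 passed between Krill-H and cHF-F, over all genes or over the list alone, while 30 lay above 0 (median 0.20; adjusted p = 0.305 with an estimated correlation, limma). Of 13 B cell genes, 0 passed between Krill-H and Krill-L, with 12 above 0 (median 0.16; adjusted p = 0.223 with an estimated correlation). Genes of the circadian clock had a median of -0.13 between Cal-L and Krill-L (16 genes, 0 called over all genes and 2 lower adjusted over the list alone; adjusted p = 0.283 with an estimated correlation).

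In Krill-H, Mcpt1, Mcpt2 and Mcpt4 lay above cHF-F by a median of 1.29. A single array does not account for all of this, since without Krill-H 1, the highest, the median was 0.994, a share of 0.771 of that with it. The 5 other members of the list had a median of 0.12 (0.09 without Krill-H 1), with Cpa3 at 0.36 and Kit at 0.19 (0.18 and 0.09 without it), Gata2 at 0.12, Hdc at 0.01 and Tpsb2 at -0.43. More mast cells of every kind cannot be told apart by this from a change in the proteases, since the 3 genes are those of smallest p in the list, so the choice puts the others lower, and Kit, Gata2 and Hdc are also made by other cells of the gut wall. A higher protease content of mucosal mast cells, or a change in that kind of mast cell alone, may remain as well and were not tested, and none of the 3 genes passed over all genes in limma (lowest adjusted p 0.158 against cHF-F).

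Genes of pancreatic acinar tissue varied widely between arrays, with list means from -3.96 to 1.86, 5 arrays over 1 and 23 under -1. Pairs of the 23 of 27 members that stand in no other list had a median r of 0.96 within diets across 48 arrays (-0.422 to 0.999), and 20 members had a median r with the others over 0.8, against -0.0442 for Spink1, 0.494 for Reg1 and 0.595 for Pnliprp2. For the 20 members this is consistent with pancreas carried over with the intestine in differing amounts. Amy2a5, the pancreatic amylase, had a mean ratio to the pool of -0.65 (SD 2.91, n = 8) in STD and -4.52 (SD 3.77, n = 8) in cHF, and Pnlip, pancreatic lipase, of -0.93 and -3.92. A diet effect cannot be told apart from this at these numbers, as the list mean differed between cHF and STD by -1.89 (95% interval -3.81 to 0.0216; two-sided exact permutation p = 0.0542 over 12870 splits, 0.486 adjusted over the 10 comparisons).

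For each comparison, 100 splits of its 16 arrays into 8 and 8, the real one included, were counted by how many called as many genes as the real one. For cHF vs STD 1 did (186 genes, highest other 1) and for Cal-L vs cHF 1 (21, highest other 3). Only the real split reached the count there, which argues against chance as the source of both counts. In Krill-H vs cHF 2 did (62, highest other 75) and in Cal-L vs cHF-F 3 (13, highest other 1736). These shares lie under 0.05, but 100 splits do not separate them reliably from it, so chance is not excluded. No share was adjusted for the number of comparisons. For Cal-L vs Krill-L 5 did (15, highest other 1332), and chance is not excluded. With a real count of 0, all 100 did for cHF-F vs cHF (highest other 1), Krill-L vs cHF (83), Krill-H vs cHF-F (0), Krill-L vs cHF-F (2) and Krill-H vs Krill-L (1). The splits with 1736 and 1332 genes call many times the real count and point to a structure of the samples: among their 100 splits they ranked 2 and 1 by their difference on the first principal component. The splits with 83 and 75 genes ranked 42 and 91 there, and none of 6 measures looked at after the result was seen accounted for them.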
